A study of Mus musculus with 6 samples.

How the data were processed

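Polyadenylated RNA was sequenced from wild-type mouse naive CD4+ T cells that had been purified from spleen and lymph nodes and cultured for 2 days under non-pathogenic (npTh17) or pathogenic (pTh17) Th17 polarising conditions, with 3 libraries per group. The cytokines used for each condition are not given in the sources used here. Per the labels' protocols, mRNA was selected with oligo-dT beads, fragmented, copied with random hexamers and size-selected before PCR, and no step that marks the strand is described.

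The deposited table holds whole-number read counts per gene and library, not normalised, with 54532 gene rows named by symbol. fastp is named in the submitters' processing notes, without a version. The aligner, the counting program, the genome build and the annotation are not given in the sources used here, so no coordinates are reported. The names of 3 columns give pTh17, day 2, wild type and a replicate number. The other 3 columns carry the name cTh17 with the same day, genotype and numbers. No label spells out cTh17. These columns were taken as npTh17 because npTh17 is the only other group of the series, and every direction reported rests on that reading. Of the rows, 27 carry a symbol turned into a date, and they hold 0.204% of the counts. They were kept in the tests and are not named. A symbol was repeated in 105 rows, and of rows that share a symbol the row with the higher total kept it.

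Total counts ranged from 15100935 to 15841419 per library. No pair of replicates agreed within sampling noise, with a chi-square per gene of 6.69 to 52.1 within groups. Nothing in the labels says whether replicates came from separate animals or cultures, so p-values measure the spread between these samples, which may be technical. Floors cover counting error only, since PCR copies cannot be told from separate molecules, while intervals and standard errors come from the spread between libraries.

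Genes with no read in any library numbered 29796. The filterByExpr function of edgeR, with its minimum count of 10 and minimum total of 15, kept 13570 genes that hold 99.85% of the counts. Libraries were scaled by TMM and tested with edgeR's quasi-likelihood test (glmQLFit and glmQLFTest), with the group as the only term. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and genes with an adjusted p under 0.05 are called changed. Fold changes are pTh17 over npTh17 on the log2 scale, and each standard error (SE) was taken from the quasi-likelihood F. Such an SE can be too small where a group has few reads. Levels are TMM-scaled counts relative to the library total (CPM), as mean ± SD over 3 libraries. For a gene with no read in a group, the fold is a lower bound against a floor of 3 counts over the group.

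Lists of genes for pathways, T helper programmes, other cell types and RNA quality, 40 in all, were fixed before the data were examined, as were the group fit, the alternatives and the rule for named genes. Each list was compared with all other genes by camera with a preset inter-gene correlation of 0.01, adjusted over the 40 lists. It was tested again with an estimated correlation, and by fry, which tests whether the genes of a list move on balance in a single direction and does not compare them with other genes. Counts of members are given over all genes tested and adjusted over the list alone.

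The genes named are 14 fixed in advance, the 8 largest rises and 8 largest falls among changed genes with an average log2 CPM of 3 or more and no overlap between groups, and up to 4 members of each list. The members are those past the threshold with the largest change and an average log2 CPM of 1 or more, or otherwise those with the lowest p. Some of these genes are not reported here. From lists of other cell types and RNA quality, up to 3 members with the highest level are named. Other members are named where 5 or fewer moved in a direction, or where a member is singled out, and these were chosen after their values were seen. Their calls were followed across the alternatives only within the counts of their lists.

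Alternatives were DESeq2 size factors, upper-quartile scaling, no filter beyond a read in any library, a filter of CPM of 1 in 3 libraries, the DESeq2 Wald test, limma-voom, the replicate number as a block, an adjusted p under 0.01, and leaving out each library in turn. Offsets for GC content and length, in 20 bins each, were added after seeing the data. GC content and length came from GENCODE mouse release M21, which matched 13483 of the tested symbols (99.4%). For 162 named genes, blastn searched the transcripts of that release for stretches of 200 bases or more at 95% identity or more in another gene. A share of 25% or more of the longest transcript, found for 16 genes, an antisense exon overlap of 25% or more, found for 5, or such an overlap on the same strand, found for 4, marks the counts as uncertain. Genes named beyond the rule were not searched, except mt-Co2 and mt-Atp6.

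The tests were tried on simulated counts with the real means, dispersions and library sizes, over 13315 genes. Few genes were changed there, with 67 by 1.5-fold, 67 by 2-fold and 66 by 4-fold, besides a list of 20. edgeR recovered 43.28% of genes changed 1.5-fold, 74.63% of those changed 2-fold and 92.42% of those changed 4-fold, with 8 false calls (5.063% of calls). False calls numbered 19 by DESeq2 (10.98% of calls) and 8 by limma-voom (5.063%). A far larger share of genes was called in the real data, and recovery depends on that share, so these rates need not hold there. In the same simulation camera called the changed list and 0 of 39 unchanged lists. Genes were simulated independently of each other there, so this count cannot show how often camera falsely calls lists of correlated genes. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and BLAST+ 2.17.0.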

Results

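Gene expression was measured by RNA sequencing in mouse naive CD4+ T cells cultured for 2 days under npTh17 or pTh17 conditions. Th17 cells are helper T cells that make interleukin 17, and pathogenic forms are those tied to autoimmune inflammation. The groups held 3 libraries each. npTh17 totals were 15841419, 15629666 and 15300377 counts, and pTh17 totals were 15181496, 15100935 and 15213001. The first principal component held 70.5% of the variance and separated the groups. The next held 11.8% and spread the npTh17 libraries, with scores of 29.5, 8.6 and -36.8 for replicates 1, 2 and 3.

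The comparison asked how the transcriptomes of the groups differ, with attention to Hmgcs1, the gene in the series title. In pTh17 cells 2293 genes rose and 2433 fell, together 34.8% of the 13570 tested. Of these, 812 rose and 826 fell at least 2-fold. The largest rise under the naming rule was that of Lum, a small proteoglycan of the extracellular matrix. It went from 0.11 ± 0.0995 to 49.9 ± 3.63 CPM (SD, n = 3), a log2 fold change of 8.73. Lum had only 0, 3 and 2 reads in npTh17, against 788, 812 and 710 in pTh17, so the size of this fold is uncertain. Gpnmb, a transmembrane glycoprotein, rose by 4.39 on the log2 scale, and Casp1, the protease that matures interleukin 1 beta, rose 19.1-fold. The other large rises under the rule were Pdzk1ip1 (18.7-fold), the glutathione transferase Gstt3 (16.8-fold), the fatty acid desaturase Scd1 (13.5-fold), the immunoglobulin gene Ighg1 (12.4-fold) and Dlg2 (11.5-fold).

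The largest fall under the naming rule was that of Ctsw, a cysteine protease of cytotoxic cells, from 243 ± 24.2 to 3.93 ± 0.614 CPM (SD, n = 3; 61.6-fold lower, adjusted p = 3.33e-10). Pdpn, the glycoprotein podoplanin, was 55.9-fold lower, Gcnt2 54.7-fold, Apol9b 54.5-fold, Peli2 50.4-fold and the scavenger receptor Stab1 44.8-fold. Aqp3, a water and glycerol channel, fell from 249 ± 38.5 to 6.45 ± 1.81 CPM. Nt5e, the ectoenzyme CD73, fell from 159 ± 26.3 to 4.65 ± 2.26 CPM. Counts of Apol9b are uncertain because Apol9a shares 97.1% of its transcript. The groups did not overlap in 6518 of the tested genes (48%), where chance gives 10%.

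**Figure D1:**
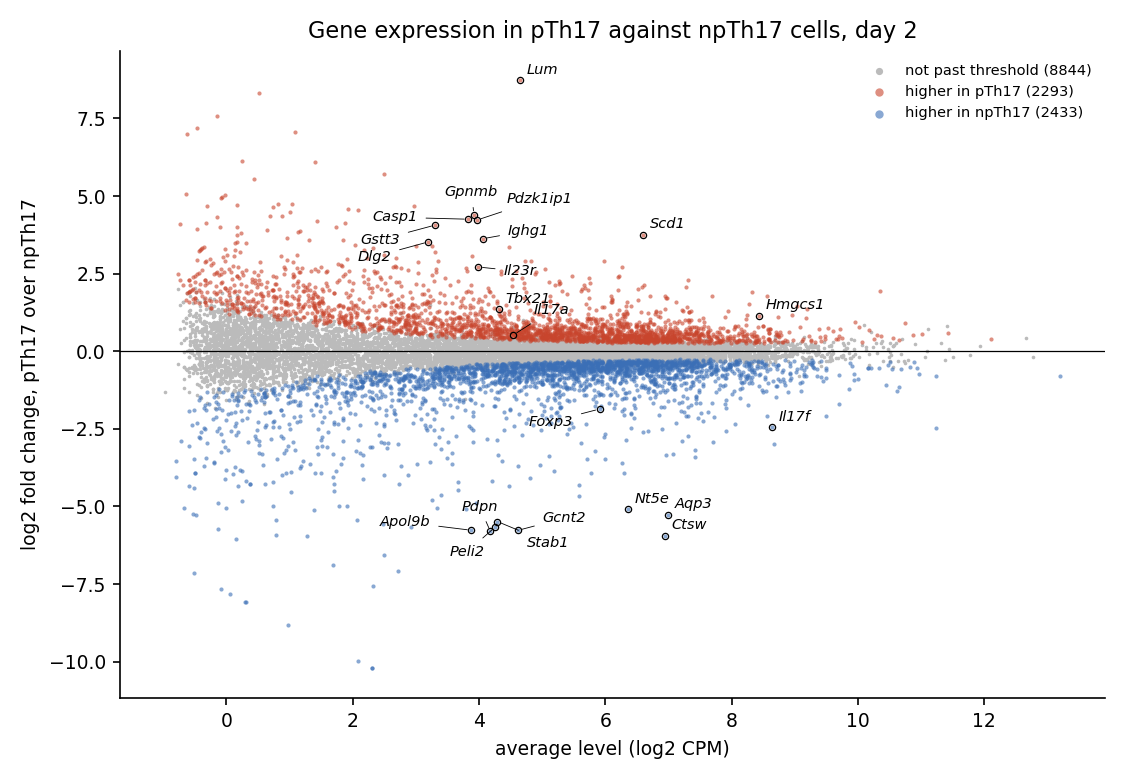
Each point is a tested gene, with its average level (log2 CPM) on the horizontal axis and its log2 fold change, pTh17 over npTh17, on the vertical axis. Red points are the 2293 genes higher in pTh17, blue points the 2433 higher in npTh17 and grey points the genes not past the threshold, and ringed genes such as Lum (8.73) and Ctsw (-5.94) are labelled.

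Genes of cholesterol synthesis rose in pTh17 cells. Hmgcs1, which makes HMG-CoA at the entry to the mevalonate pathway, went from 217 ± 25.6 to 480 ± 46.6 CPM (SD, n = 3), a log2 fold change of 1.15 (SE 0.12, adjusted p = 1.25e-05), with all pTh17 libraries above all npTh17 libraries. Of its transcript 13.3% is shared with the antisense gene Gm48342. Sqle, the squalene epoxidase, rose by 0.55 on the log2 scale. Of the 21 genes of the list, 19 rose and none fell, with the same 19 adjusted over the list alone, and the median fold was 1.66. Lss, which closes the sterol ring, rose most (log2 fold change 1.43), followed by Hmgcs1, Dhcr7 (1.11) and Fdps (1.09). Ggps1 and Ebp did not pass, and counts of Fdps are uncertain because 26.7% of its exon bases overlap Gm43738. The list stood above the other genes (adjusted p = 1.8e-07 by camera), a call that was lost with an estimated correlation (adjusted p = 0.28 with an estimated correlation).

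Sterol-sensing and uptake genes went both ways. Srebf2, the transcription factor that drives sterol genes, had a log2 fold change of 0.13 (adjusted p = 0.354). Of the 13 members tested, 4 rose, among them Insig1, Stard4 and Scarb1, and 3 fell (Npc1, Lipa and Scap), with 4 and 3 adjusted over the list alone, and the list did not stand apart (adjusted p = 0.5). Among 11 sterol efflux and oxysterol genes, 3 rose and 4 fell, also adjusted over the list alone, and the list did not stand apart (adjusted p = 0.97). Gpr183, a receptor for oxysterols, rose 2.5-fold, the exporter Abcg1 rose 1.81-fold and Lpcat3 rose too, while Osbpl3, Mylip, Soat1 and Nr1h2 fell. The count of 4 falls became 2 without npTh17 replicate 2, pTh17 replicate 1 or pTh17 replicate 2.

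Desaturases led the fatty acid synthesis list. Scd1 rose from 13.3 ± 1.98 to 181 ± 13.1 CPM, Scd2 from 539 ± 101 to 2070 ± 31.8 CPM and Fads2 from 23.1 ± 2.92 to 125 ± 6.77 CPM (SD, n = 3). In all, 8 of 16 members rose (9 adjusted over the list alone) and 1 fell, Acacb, which limits fatty acid oxidation (log2 fold change -2.27). The list stood above the other genes (adjusted p = 0.0026; adjusted p = 0.4 with an estimated correlation). Without pTh17 replicate 3 the rises numbered 5, and without pTh17 replicate 1 the falls numbered 2.

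**Figure D2:**
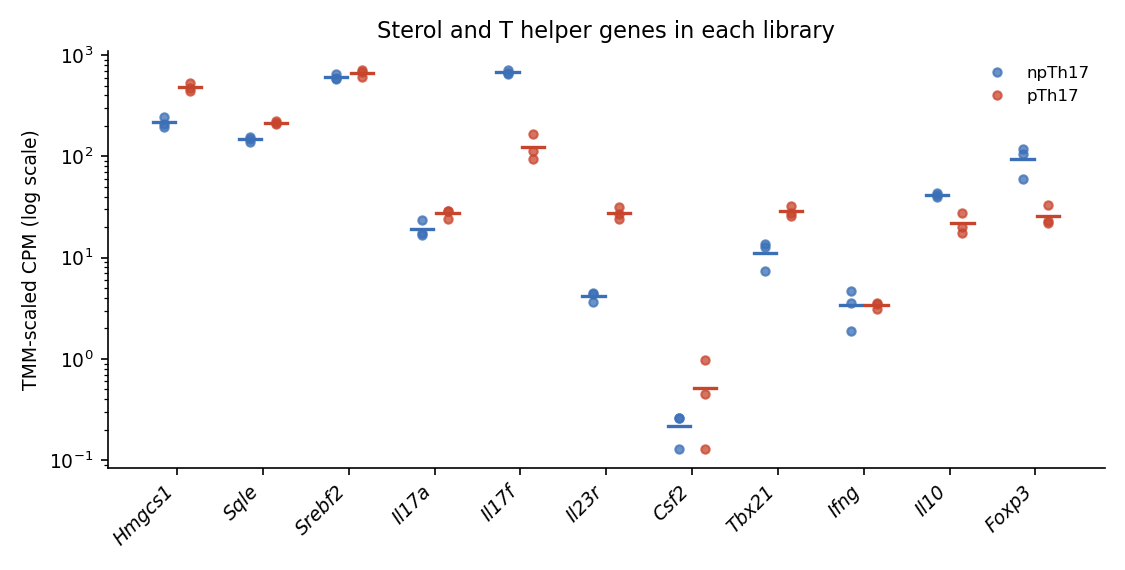
Points show TMM-scaled CPM on a log scale in each of the 3 npTh17 (blue) and 3 pTh17 (red) libraries for genes fixed in advance, and bars show group means. Hmgcs1 lies at a mean of 217 CPM in npTh17 and 480 CPM in pTh17, and Il17f at 675 and 125 CPM.

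More genes of the Th17 lineage fell than rose in pTh17 cells. Il17f fell from 675 ± 29.1 to 125 ± 38 CPM (SD, n = 3; log2 fold change -2.44). Il17a went the other way, from 19.1 ± 3.67 to 27.3 ± 2.64 CPM (log2 fold change 0.52, SE 0.16, adjusted p = 0.0236). Il23r, the receptor for the cytokine that sustains pathogenic cells, rose 6.56-fold. Ahr and Maf, transcription factors tied to interleukin 10, fell 10.6-fold and 7.96-fold, and the chemokine gene Ccl20 fell 14.4-fold. Over the Th17 lineage list 10 of 20 members fell (11 adjusted over the list alone) and 3 rose, Il23r, Batf and Il17a (3 adjusted over the list alone), and the list stood below the other genes (adjusted p = 0.011; adjusted p = 0.34 with an estimated correlation). The call for Il17a was lost without npTh17 replicate 2 (adjusted p = 0.107), pTh17 replicate 1 (0.0937) or pTh17 replicate 2 (0.087).

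The pathogenic Th17 list was mostly higher in pTh17 cells, with 10 of 15 members up and 4 down, also adjusted over the list alone (adjusted p = 0.0091; adjusted p = 0.29 with an estimated correlation). Casp1, Il23r and the cytotoxic protease gene Gzmb (6.29-fold) rose, as did Tbx21, the Th1 master factor T-bet (2.56-fold). The members that fell were Lgals3 (7.67-fold lower), Ccl4, Il7r and Lag3. Csf2, the gene for GM-CSF, had too few reads to be tested, with 4, 4 and 2 in npTh17 and 7, 15 and 2 in pTh17. Of the 7 non-pathogenic Th17 genes, 6 fell and none rose, also adjusted over the list alone (adjusted p = 9.9e-05; adjusted p = 0.3 with an estimated correlation). Besides Ahr and Maf these included Il6st, the shared receptor chain for interleukin 6 (4.78-fold lower), Ikzf3 (2.48-fold) and Il10, from 41.7 ± 2.12 to 21.7 ± 5.17 CPM (SD, n = 3). Il1rn was at 6.41 and 5.79 CPM (log2 fold change -0.15). Il23r is in the lineage and pathogenic lists, and Maf and Ahr are in the lineage and non-pathogenic lists.

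Th1 genes rose in part. Gzmb, the chemokine receptor Cxcr3 (3.78-fold), Il18rap (3.41-fold) and Stat4 (3.4-fold) led 7 rises among 17 members (9 adjusted over the list alone), and Prf1 and Runx3 fell (2 adjusted over the list alone). Ifng, the hallmark Th1 cytokine gene, was at 3.38 ± 1.42 and 3.39 ± 0.254 CPM (SD, n = 3; log2 fold change 0.01, adjusted p = 0.989), with uncertain counts since 25.9% of its exon bases overlap Gm49751. The list stood above the other genes (adjusted p = 0.011; adjusted p = 0.29 with an estimated correlation). Counts of Stat4 are uncertain, since Gm28177 shares 26.7% of its transcript.

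Th2 genes were split. The receptor Ccr4 (2.4-fold), the cytokine gene Il13 (2.4-fold) and Gata3 rose, and Ccr8 (6.75-fold lower), Il1rl1 and Il4ra fell, so 3 of 8 moved each way, also adjusted over the list alone, and the list did not stand apart (adjusted p = 0.87). Its median (0.49) and test were up and its mean (-0.06) down. Il13 lost its call without pTh17 replicate 2 (adjusted p = 0.054), and Il1rl1 without pTh17 replicate 1 (0.0753) or pTh17 replicate 2 (0.0539). Of 9 follicular helper genes, Btla (3.76-fold), Icos (2.56-fold), Sh2d1a and Bcl6 rose, and Cxcr5, Pdcd1 and Tox2 fell, with 4 and 3 adjusted over the list alone. That list did not stand apart (adjusted p = 0.53), with its median (-0.16) down and its mean (0.30) and test up. Its falls numbered 1 without npTh17 replicate 2 and 5 without npTh17 replicate 3, and Sh2d1a overlaps Tenm1 on the other strand, so its counts are uncertain.

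Many regulatory T cell genes and targets of TGF-beta, a cytokine that restrains T cells, were lower in pTh17 cells, and others were higher. Foxp3, the regulatory T cell factor, fell from 94.2 ± 30.6 to 25.9 ± 6.24 CPM (SD, n = 3; 3.63-fold lower), together with Nt5e, Itgae (7.16-fold), Capg (4.25-fold) and Lrrc32 (3.96-fold). Of 16 regulatory T cell genes 9 fell (10 adjusted over the list alone) and 4 rose (5 adjusted over the list alone), the latter being Tnfrsf9, Ctla4, Tnfrsf4 and Ikzf2. The list call (adjusted p = 0.026; adjusted p = 0.43 with an estimated correlation) was lost without npTh17 replicate 1 (adjusted p = 0.061) or pTh17 replicate 2 (0.052). In the TGF-beta response list 14 of 22 members fell (16 adjusted over the list alone) and 4 rose, among them Id3, Bmpr1a and Id2 (4 adjusted over the list alone; adjusted p = 4.9e-05; adjusted p = 0.3 with an estimated correlation). The receptor gene Tgfbr1 fell from 260 ± 32 to 35 ± 0.722 CPM, Smad7 4.4-fold and Ldlrad4 10.4-fold. Smad6 had 75 reads in npTh17 and 0 in pTh17, at least 25.2-fold higher in npTh17, and the list median of -1.14 is the same with Smad6 at that bound. Ldlrad4 counts are uncertain, since 84.2% of its transcript is shared with the antisense gene Fam210a.

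**Figure D3:**
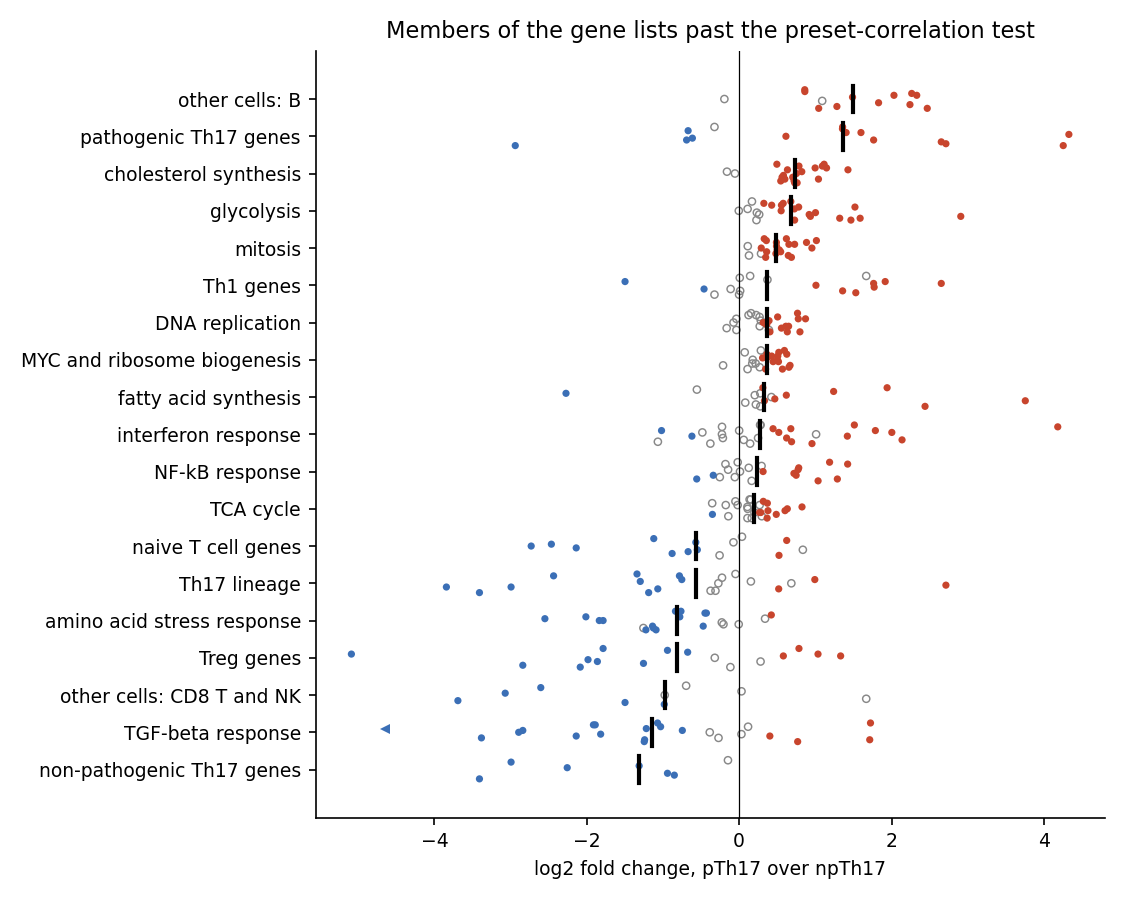
Each row is a gene list past the camera test with a preset correlation, and each point a tested member, placed by its log2 fold change, pTh17 over npTh17. Red and blue points passed the threshold, open points did not, the triangle marks Smad6 at its bound of at least 25.2-fold, and black bars mark medians, from 1.49 for the B-cell list to -1.31 for non-pathogenic Th17 genes.

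NF-kB target genes rose on balance. Tnf (2.68-fold), Traf1 (2.44-fold), Nfkbiz (2.28-fold) and Bcl2a1b were among 9 of 20 that rose, also adjusted over the list alone, and Nfkb1 and Bcl3 fell (3 adjusted over the list alone). The list call (adjusted p = 0.039; adjusted p = 0.3 with an estimated correlation) was lost without npTh17 replicate 1 (0.1), pTh17 replicate 1 (0.058) or pTh17 replicate 2 (0.056). The list median of 0.23 became 0.11 without npTh17 replicate 1 and 0.15 without pTh17 replicate 2, and the falls numbered 1 without npTh17 replicate 2 or any pTh17 replicate. All of the Bcl2a1b transcript is shared with its paralogs, so its counts are uncertain.

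Interferon response genes rose in part, with 12 of 27 up and 2 down (Irf7 and Socs1), also adjusted over the list alone (adjusted p = 0.011; adjusted p = 0.3 with an estimated correlation). Mx1 rose from 0.259 ± 0.231 to 4.88 ± 0.575 CPM, Ifih1 4.4-fold, and the guanylate-binding protein genes Gbp5 and Gbp2 4.01-fold and 3.45-fold. The falls numbered 1 without pTh17 replicate 2 or 3, and the median of 0.28 became 0.47 without npTh17 replicate 1. Of 16 STAT3 response genes 8 fell and 3 rose, also adjusted over the list alone, and the list did not stand apart (adjusted p = 0.08), though it did with limma-voom (0.025) and with no filter (0.026). Il6st, the feedback inhibitor Socs3 (3.91-fold) and Il6ra (2.37-fold) fell, while Batf and Pim2 rose and Osmr, with 0 reads in npTh17, was at least 18.2-fold higher in pTh17. The STAT3 list median of -0.28 is the same with Osmr at that bound.

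Interleukin 1 family genes moved both ways, with 6 of 16 up (7 adjusted over the list alone) and 4 down (5 adjusted over the list alone; adjusted p = 0.53). Il18rap, Il1rl2 (3.3-fold) and the decoy receptor Il1r2 (3.09-fold) rose. Traf6 fell 2.95-fold, and Il1rl1, Irak4 and Myd88 fell too. The falls numbered 2 without pTh17 replicate 2, and Il1rl1 lost its call without pTh17 replicate 1 (adjusted p = 0.0753) or pTh17 replicate 2 (0.0539). Among 17 interleukin 2 and STAT5 response genes 6 rose (7 adjusted over the list alone) and 6 fell, also adjusted over the list alone (adjusted p = 0.95), with the median (-0.17) down and the mean (0.18) and test up. Il2 rose from 17.5 ± 3.15 to 89.4 ± 4.83 CPM (SD, n = 3), Tnfrsf8 4.39-fold and Prdm1 2.69-fold, while Socs2 fell 2.31-fold.

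Cytokine genes did not move as a group (adjusted p = 0.87), the median (-0.18) being down and the mean (0.13) and test up, with 11 of 27 up and 10 down (11 and 11 adjusted over the list alone). Besides Il2, the subunit gene Ebi3 rose 6.27-fold, while Ccl20 and Il17f fell. Of 21 chemokine receptor and homing genes, 9 fell (10 adjusted over the list alone), led by Itgae, Ccr8 and S1pr1 (4.41-fold), and 4 rose, Ccr1 (5.95-fold), Cxcr3, Ccr4 and S1pr2 (4 adjusted over the list alone; adjusted p = 0.23).

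Among naive T cell genes 8 of 14 fell, also adjusted over the list alone, and 2 rose, Lef1 and Satb1 (3 adjusted over the list alone). Klf2 fell 6.63-fold, S1pr1, the receptor for exit from lymph nodes, 4.41-fold, Itga6 2.17-fold, and Igfbp4 from 4090 ± 876 to 742 ± 105 CPM (SD, n = 3). The list call (adjusted p = 0.026; adjusted p = 0.48 with an estimated correlation) was lost without npTh17 replicate 1 (adjusted p = 0.1). Of 22 activation and AP-1 genes, 7 rose and 5 fell, also adjusted over the list alone (adjusted p = 0.79), with a median of 0 and the mean (0.11) and test up, and with Cd40lg (3.58-fold), Batf3 and Tnfsf8 up and Nr4a3, Jun, Nr4a1, Fosl2 and Egr2 down. Co-inhibitory receptors were split, with Cd200 (4.93-fold), Btla, Tigit and Ctla4 up and Pdpn, Entpd1, Pdcd1 and Lag3 down, 4 each of 12, also adjusted over the list alone (adjusted p = 0.77). The median (0.16) and test were up and the mean (-0.17) down.

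Glycolysis genes rose in pTh17 cells, with 17 of 23 up and none down, also adjusted over the list alone (adjusted p = 2.2e-07; adjusted p = 0.28 with an estimated correlation). The lactate exporter Slc16a3 rose 3.01-fold, Aldoc 2.87-fold, and Tpi1 from 277 ± 31.9 to 766 ± 50.6 CPM (SD, n = 3). Gapdh had 253, 218 and 207 reads in npTh17 and 3404, 827 and 933 in pTh17, a log2 fold change of 2.91 (SE 0.44) that was 1.94 without pTh17 replicate 1. Its counts are uncertain, since 90 other genes carry near-identical stretches. Hypoxia response genes went both ways, with 8 of 18 up and 5 down, also adjusted over the list alone (adjusted p = 0.25). Egln3, an oxygen sensor, fell 3.18-fold and Vegfa 2.89-fold, while Ankrd37 and Bnip3 rose, both with uncertain counts from overlapping or near-identical genes.

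Of 25 genes of the TCA cycle, 10 rose and 1 fell, Pdha1, also adjusted over the list alone (adjusted p = 0.017; adjusted p = 0.3 with an estimated correlation), led by Pcx (1.77-fold), Idh1 (1.55-fold), Sdhd (1.52-fold) and Dlst (1.4-fold). The list call was lost without npTh17 replicate 1 (0.061), where 2 members fell. The rises numbered 6 without npTh17 replicate 2 or pTh17 replicate 2 and 5 without pTh17 replicate 1 or 3, the fall of Pdha1 was lost without any library but npTh17 replicate 1, and Idh1 lost its call without npTh17 replicate 2 (0.0657) or pTh17 replicate 3 (0.07). Of 33 genes of oxidative phosphorylation, 5 passed (1 adjusted over the list alone), all higher, Cox7a2 (1.64-fold), Cox6c, Atp5o, Cox5b and Cycs, and the list did not stand apart (adjusted p = 0.15). It did without npTh17 replicate 3 (0.0055), with 13 rises, and the rises numbered 2 without npTh17 replicate 1, where 2 members fell, or pTh17 replicate 2, and 1 without npTh17 replicate 2, pTh17 replicate 1 or pTh17 replicate 3. npTh17 replicate 3 held 0.579% mitochondrial reads against 1.33% to 2.27% in the other libraries. Cox6c lost its call without npTh17 replicate 1 or 2 or pTh17 replicate 1 or 3 (adjusted p of 0.0598 to 0.143). Atp5o lost its call without npTh17 replicate 2 or any pTh17 replicate (0.0624 to 0.138), and Cox5b without any library but npTh17 replicate 3 (0.0732 to 0.207). With no filter Atp5o (0.0507) and Cox5b (0.0592) did not pass. With GC and length offsets the rises numbered 9. Atp5o and Cox5b also have uncertain counts from shared or overlapping genes.

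Fatty acid oxidation genes did not stand apart (adjusted p = 0.72), with 4 of 15 down (Cpt1a, Ppard, Slc25a20 and Acadvl) and 2 up, Acadl and Hadh (4 and 3 adjusted over the list alone). Cpt1a, which admits fatty acids to mitochondria, fell 3.17-fold. The rises numbered 4 without npTh17 replicate 3 and 1 without pTh17 replicate 1 or 3, and Acadvl counts are uncertain, since Dvl2 overlaps it on the other strand.

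Genes of the amino acid stress response fell in pTh17 cells, with 14 of 20 down (15 adjusted over the list alone) and 1 up, Ddit3 (1 adjusted over the list alone; adjusted p = 9e-06; adjusted p = 0.29 with an estimated correlation). Asns, which makes asparagine, fell from 136 ± 16.3 to 33.7 ± 1.27 CPM (SD, n = 3), Pycr1 5.86-fold, Trib3 3.57-fold and Chac1 3.45-fold. The call for Ddit3 was lost without any library but npTh17 replicate 1. Atf4, the factor that drives this response, had a log2 fold change of -0.01 (adjusted p = 0.974). Glutamine and amino acid transport genes were split, with 4 of 19 up and 4 down, also adjusted over the list alone (adjusted p = 0.77), with a median of 0 and the mean (-0.18) and test down. Gpt2 (4.42-fold), Slc7a11 (4.1-fold), Slc7a5, the large neutral amino acid carrier (2.16-fold), and its partner Slc3a2 fell. Got2, Srm and Amd1 rose, and Sms rose 2.76-fold, with uncertain counts since 3 other genes share 29.6% of its transcript. Of 21 unfolded protein response genes 2 rose, Atf6 and Edem1, and 3 fell, Herpud1, Xbp1 and Pdia4, also adjusted over the list alone (adjusted p = 0.92). The rises numbered 5 without npTh17 replicate 3 and 1 without npTh17 replicate 1 or 2 or pTh17 replicate 1 or 2, and Pdia4 lost its call without pTh17 replicate 2 (0.0506).

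Growth and division genes rose in pTh17 cells. Of 22 mitosis genes 19 rose and none fell, also adjusted over the list alone (adjusted p = 1.2e-06; adjusted p = 0.29 with an estimated correlation), led by Ccnb1, from 108 ± 5.04 to 218 ± 3.14 CPM (SD, n = 3), Plk1 (1.94-fold), Cdk1 (1.85-fold) and Hmmr (1.66-fold). Among 25 DNA replication genes 14 rose (17 adjusted over the list alone) and none fell (adjusted p = 9.9e-05; adjusted p = 0.3 with an estimated correlation), with Ccne2 (1.83-fold), Mcm10 (1.74-fold), Tyms (1.71-fold) and Cdc6 (1.7-fold) in front. Of 23 MYC and ribosome biogenesis genes 15 rose and none fell, also adjusted over the list alone (adjusted p = 0.00014; adjusted p = 0.32 with an estimated correlation), with Ppan, Srm, Utp20 and Gnl3 in front (1.51-fold to 1.59-fold). Myc itself had a log2 fold change of -0.21 (adjusted p = 0.189). The rises numbered 8 for DNA replication without pTh17 replicate 3, and 9 for ribosome biogenesis without npTh17 replicate 2, pTh17 replicate 1 or pTh17 replicate 2. Without npTh17 replicate 3, 1 ribosome biogenesis gene fell. Ccnb1, Cdc6 and Tyms have uncertain counts from near-identical stretches in other genes.

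Markers of B cells were higher in pTh17 libraries. Ighm went from 143 ± 20 to 349 ± 22.9 CPM, Igkc from 13.3 ± 2.07 to 63.8 ± 2.29 CPM and the B-lineage factor Pax5 from 10.3 ± 1.42 to 42.2 ± 8.01 CPM (SD, n = 3). Of 13 markers 11 rose (12 adjusted over the list alone) and none fell (adjusted p = 1.2e-06; adjusted p = 0.29 with an estimated correlation). CD8 T and NK markers were lower, with 5 of 9 down, Klrd1 (12.9-fold), Klrc1, Klre1, Prf1 and Cd8a, and none up (5 and 1 adjusted over the list alone), while Cd8b1 was at 6.91 and 7.06 CPM. That call (adjusted p = 0.039; adjusted p = 0.32 with an estimated correlation) was lost without npTh17 replicate 3 (0.079), pTh17 replicate 2 (0.066) or pTh17 replicate 3 (0.056), and 1 member rose without npTh17 replicate 2. Prf1 is also a Th1 gene and Eomes is in both lists.

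Other cell types did not stand apart as lists. Among 5 gamma-delta T cell genes Trdc (3.15-fold), Tcrg-C1 and Tcrg-C2 fell and Blk rose, also adjusted over the list alone (adjusted p = 0.13), with 1 fall among the 2 members that passed the CPM filter. Among 11 myeloid and dendritic genes Cd74 rose 1.59-fold and Ly6g, Lyz2 and Zbtb46 fell, also adjusted over the list alone (adjusted p = 0.77). The median (0.16) was up and the mean (-0.82) and test down, with Cst3 at 43.6 and 36.5 CPM and H2-Ab1 at 26.1 and 31.7 CPM. Among 5 erythroid, platelet and stromal genes 1 fell, Pdpn, also adjusted over the list alone (adjusted p = 0.27), and 3 fell with no filter, with Pecam1 at 60.4 and 63.6 CPM and Hbb-bs at 2.82 and 2.38 CPM.

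Signs of RNA quality varied between libraries. Mitochondrial reads made up 2.16%, 1.33% and 0.579% of npTh17 counts and 1.98%, 1.84% and 2.27% of pTh17 counts. Of 14 mitochondrial transcripts, mt-Atp6 rose and mt-Co2 fell (1 and 0 adjusted over the list alone), and the list did not stand apart (adjusted p = 0.17). Without npTh17 replicate 1 it did (0.0083), with 11 rises, and mt-Co2 then had a log2 fold change of -0.06 (adjusted p = 0.818). With all libraries mt-Co2 was at an adjusted p of 0.0499, and its call was also lost without any pTh17 replicate, by DESeq2 or limma-voom, with upper-quartile scaling and with the CPM filter. The rises numbered 2 without npTh17 replicate 3, pTh17 replicate 2 or pTh17 replicate 3, 11 with no filter and 3 by DESeq2. mt-Co1 was at 5540 ± 3150 and 7370 ± 717 CPM (SD, n = 3), mt-Cytb at 1960 and 3470 CPM and mt-Nd1 at 1670 and 2760 CPM, none past the threshold. Each passed without npTh17 replicate 1 and with no filter, and mt-Cytb also without npTh17 replicate 3 (adjusted p = 0.0418). Of 15 dissociation and heat shock genes Hspd1, Fos, Hsp90aa1 and Hspe1 rose and Jun, Ier2 and Dnajb1 fell, with 4 and 3 adjusted over the list alone (adjusted p = 0.53), while Hsp90ab1 was at 3670 and 4120 CPM and Hspa8 at 2700 and 2870 CPM. The rises numbered 2 without npTh17 replicate 2 or pTh17 replicate 2, and the falls 1 without npTh17 replicate 2 or any pTh17 replicate. Counts of mt-Co1, Hsp90aa1 and Hspa8 are uncertain because of near-identical copies.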

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

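The GC and length offsets were chosen after the results were seen. The count of changed genes was 2926 at an adjusted p under 0.01, fewer by construction of the stricter threshold. All 19 list calls were lost with an estimated correlation, leaving 0 of 40 lists (6 at an unadjusted p under 0.05), and the cholesterol synthesis list then had an adjusted p of 0.28. The 2 forms of camera differ in more than the correlation. With an estimated correlation the degrees of freedom come from the 6 libraries, and with the preset from the number of genes. The estimated form therefore has less power here, and its adjusted p-values are not evidence that a list is unchanged. How much of the loss comes from this was not tested. Correlation among members cannot account for the loss in every list. The Th1 list, and the STAT3 list, which was not among the 19, had estimated correlations of -0.043 and -0.028, under the preset 0.01. Their unadjusted camera p still went from 0.0038 to 0.036 and from 0.04 to 0.092. By fry, which asks another question, 25 lists passed. Leaving out each library in turn gave 3462 to 5606 changed genes, 1559 to 2716 higher, 1879 to 2890 lower and 1531 to 1748 changed at least 2-fold. The cholesterol list's adjusted p ranged from 2.2e-07 to 1e-06, the Hmgcs1 log2 fold change from 1.05 to 1.24, and the lists past the threshold from 16 to 19. Under other scalings, filters, tests and offsets the changed genes numbered 4603 to 5144, and the share of calls that were higher stayed between 47.8% and 49.9%. Of the 4726 changed genes, 4652 were also called by the DESeq2 Wald test, 4624 by limma-voom, 4440 with no filter and 4406 with the offsets.

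Same-numbered libraries showed little joint deviation, with correlations across genes of -0.07, 0.08 and 0.05, against -0.11 to 0.04 for libraries of different numbers. With 3 libraries per group these values cannot decide whether the numbers pair the samples. With the replicate number as a block, 4662 genes changed (2276 higher, 2386 lower, 1594 at least 2-fold), Hmgcs1 had a log2 fold change of 1.15, the cholesterol list an adjusted p of 8.1e-07, and 16 lists passed. The regulatory T cell (0.058), NF-kB (0.059) and CD8 T and NK (0.057) lists were then not past the threshold. Among mitochondrial transcripts 6 then rose and 0 fell, among them mt-Cytb (adjusted p = 0.0332) and mt-Nd1 (0.0358).

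The alternatives for normalised values were not run because the table holds counts, and gene lists were not tested with DESeq2. With the CPM filter the gamma-delta T list had too few members to test. Of 160 named genes tested besides Hmgcs1, 147 passed the threshold, and 139 of these also passed under every alternative run. The other 8 (Atp5o, Cox5b, Cox6c, Idh1, Il13, Il17a, Il1rl1 and Pdia4) were lost under at least 1, and no named gene reversed. Depth limits genes such as Csf2, with 2 to 15 reads per library.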

Other observations

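The gene families and their limit to protein-coding genes, the GC and length offsets, the tests of B-lineage genes, the test of a split of reads as the whole cause of the Gapdh rise and the separate tests of mt-Co2 and mt-Atp6 were chosen after the results were seen. Protein-coding genes that share the letters at the start of their symbol were grouped into 340 families with 5 or more tested members. Each family's count of calls was compared with all other tested protein-coding genes by Fisher's exact test in each direction, 680 tests in all. The 5 past an adjusted p of 0.05 were also past it under DESeq2 size factors and upper-quartile scaling, but each lost its call without at least 1 library. Fisher's test takes the genes of a family as independent, so its p-values may be too small where members move together. All 8 tested guanylate-binding protein genes rose in pTh17 (adjusted p = 0.00035, median log2 fold change 1.32), led by Gbp5 (4.01-fold) and including 4 of the interferon list. Without pTh17 replicate 3 the family had 5 rises (adjusted p = 0.14). The Ifi genes went the other way, with 9 of 11 lower (adjusted p = 0.0037), among them Ifi208 (22.4-fold), Ifi206 (9.83-fold) and Ifi213 (8.58-fold), while Ifi211 rose 6.58-fold and Ifi27l2a 2.72-fold. The Ifi call was lost without npTh17 replicate 3 (0.088), pTh17 replicate 1 (0.071) or pTh17 replicate 2 (0.066).

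Of 77 mitochondrial ribosomal protein genes 32 rose and Mrpl24 fell, more rises than among other genes (adjusted p = 0.00035, median log2 fold change 0.3), and the rest did not pass. The rises numbered 21 without npTh17 replicate 2 (adjusted p = 0.068), 17 without pTh17 replicate 1 (0.51) and 20 without pTh17 replicate 3 (0.13). All 5 replication factor C genes rose (adjusted p = 0.031), with Rfc3 2.09-fold higher, but the family passed only without npTh17 replicate 1 (0.028) when libraries were left out in turn (0.24 to 0.62 without the others). Of 7 Smad genes, which carry or, as Smad6 and Smad7, inhibit TGF-beta and BMP signals, 6 fell (adjusted p = 0.046). Of these, Smad3, Smad6 and Smad7 are also in the TGF-beta list. The largest falls were those of the inhibitory Smad6 and Smad7, while Smad4 had a log2 fold change of -0.34 and Smad2 of 0.01. The Smad call was lost without npTh17 replicate 3 (0.088), pTh17 replicate 1 (0.19) or pTh17 replicate 3 (0.14). The Galnt genes (7 of 11 lower, adjusted p = 0.17), S100a genes (5 of 7 higher, 0.2) and Gimap genes (5 of 8 higher, 0.33) did not pass as families, though S100a4 rose 12.1-fold and Gimap7 6.04-fold. The metallothionein genes Mt1 and Mt2 rose 5.95-fold and 4.88-fold.

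The other splits of the 6 libraries into 3 and 3 gave at most 0 changed genes, 0 higher, 0 lower and 0 changed at least 2-fold by edgeR, against 4726, 2293, 2433 and 1638 for the real groups. At an unadjusted p under 0.05 they gave 57 to 699 genes, against 6048, and other tools were not run on them. For gene lists the real groups gave 19 and the highest other split 13. With 10 splits, of which 1 gave as many of each, no share under 0.05 can be reached. Every other split mixes libraries of both groups, so the difference between the groups counts there as spread within a side. Low counts of genes in these splits follow from that mixing and do not show how many calls arise without a difference.

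B-lineage genes were higher in pTh17, and B cells left over from the purification of naive CD4+ T cells are a candidate source. B cells carry abundant MHC class II transcripts. H2-Aa, H2-Ab1 and H2-Eb1 had a median gain of 1.61 CPM, against 31.9 CPM for Pax5 (95% interval 18.8 to 44.9). This cannot decide on whole B cells as a source. Class II transcripts were already at 21 to 29.8 CPM in npTh17. They are shared with myeloid and dendritic cells, whose markers Ly6g, Lyz2 and Zbtb46 fell, so a loss there could hide a gain from B cells. Cd74, whose product escorts MHC class II, did gain 53.7 CPM. A larger share of a single B-cell source already in npTh17 would raise all markers by the same fold, but the 13 members differed beyond their errors (Cochran's Q = 134, where equal folds give 12 on average), from Ighd (log2 fold change -0.19) to Blnk (2.47). Leftover B cells stay open as a source. Transcription of these loci by the T cells, or B cells in another state, may also account for the rise, and neither was tested.

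Cholesterol synthesis, glycolysis and mitosis genes rose together. Bias of the libraries in GC content or length could move lists of genes, but with offsets for both, which moved single genes by up to 0.368 on the log2 scale, the medians were 0.67, 0.66 and 0.48, against 0.73, 0.68 and 0.49 without. This argues against such bias as the whole cause. A joint rise that goes with the polarising condition stays open as a hypothesis, since a difference in growth rate or in the mix of cells was not tested.

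Gapdh, mt-Co2 and mt-Atp6 had uneven counts and have near-identical copies, so reads may have been split between copies differently in each library. Summed with its 90 copies in the table, Gapdh still rose by 1.61 on the log2 scale (SE 0.29, adjusted p = 0.0011; 1.07 without pTh17 replicate 1, still past the threshold), which argues against a split as the whole cause, but next to 1.59 for Slc16a3, the highest other glycolysis gene, a split as the cause of the excess in Gapdh alone (2.91) cannot be told apart from a rise of Gapdh itself. For mt-Atp6 the sum still rose by 1.54 (SE 0.44, adjusted p = 0.0169), which argues against a split between rows of the table as the whole cause, though it was 1.42 without npTh17 replicate 2 (0.0776) and 1.28 without pTh17 replicate 2 (0.0812), neither past the threshold, and 2.37 without npTh17 replicate 1. mt-Co2 stood out in npTh17 replicate 1 alone, where the sum was 3013 reads against 587 to 733 in the other libraries (3.95 times the highest of them in CPM, where those differed by up to 1.24 times) and the copies, at 627 reads against 279 to 353, were not depleted, which argues against a split as the whole cause; the fall of the sum between groups, -1.17 (adjusted p = 0.0545), was -0.12 without that library, -1.5 without npTh17 replicate 2 (0.0252) and -1.52 without npTh17 replicate 3 (0.00107). Summing covers only reads assigned to rows, so reads discarded as multi-mapped stay open.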
